A study of Drosophila melanogaster with 12 samples.

How the data were processed

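RNA was sequenced from midguts of adult virgin Drosophila melanogaster of both sexes. In 1 genotype an RNA interference construct against dsx (dsxRNAi) was driven in enterocytes, and in the control genotype the same driver was combined with UAS-GFP. The libraries were made with a poly-A, strand-specific kit from 200 ng of RNA and sequenced as read pairs of 100 bp, per the labels' protocols. There were 12 libraries in 4 groups of 3: dsxRNAi females, control females, dsxRNAi males and control males.

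The deposited table holds raw read counts per gene for the 12 libraries. Reads were aligned with TopHat2 2.0.11 to build dm6 and assigned to genes with featureCounts, per the submitters' processing notes. The strand setting, the annotation release and any read filter are not given in the sources used here. The table has 17558 rows. Of these, 171 rows without a symbol hold 2.17% of all counts and were tested but not named. Gene positions were taken from an Ensembl annotation on dm6 coordinates, in which 17252 row identifiers were found.

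Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 9686 genes, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with 4 group means and robust dispersion was fitted to all 12 libraries in 1 fit. The 5 contrasts tested were dsxRNAi against control in females, the same in males, females against males in controls, females against males under dsxRNAi, and the difference between the female and the male dsxRNAi effect, called the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that contrast. Adjusted p-values given for genes come from this edgeR test, and fitted log2 changes from edgeR with a prior count of 0.125. Levels are TMM-scaled CPM, the counts of a gene relative to the effective library size (normalised CPM), as mean ± SD of 3 libraries. Levels of single genes were also compared by an exact two-sided permutation test, which with 3 libraries against 3 cannot go below p = 0.1.

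The 35 gene lists were written before the data were examined, as were the 5 contrasts, the tests, the alternative settings and the rule for naming genes. They cover sex determination and dosage compensation, described doublesex targets, lipid synthesis and storage, lipolysis and fatty acid oxidation, lipid digestion and transport, starch and sugar digestion, sugar sensing and glycolysis, digestive serine proteases, lysozymes, antimicrobial and Imd pathway genes, heat shock proteins, detoxification enzymes, the Myc network and ribosome biogenesis, ribosomal proteins, the respiratory chain and ATP synthase, the proteasome, the cell cycle, JAK-STAT and EGF receptor signalling, insulin and TOR signalling, metal handling, regional transcription factors, genes marked or driven in the genotypes and Y-linked genes. The other lists hold markers of progenitors, enteroendocrine cells, enterocytes, copper cells, visceral muscle, Malpighian tubule, fat body and hemocytes, trachea, neurons, testis, male accessory gland and ovary. No Y-linked or accessory gland gene passed the expression filter, so 33 lists were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry. Adjustment for lists was over the 33 lists of a contrast. Beside each list stands its number of called members, over all genes and adjusted over the list alone.

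Genes were named by a rule. It covers dsx and the sex determination list, the 6 largest positive and 6 largest negative changes among called genes with a mean log2 CPM of at least 1 and group ranges that do not overlap (no overlap rule for the interaction), up to 4 called members of each list with the smallest p, up to 2 abundant members of lists without a call, as values only, and the genes marked or driven in the genotypes (y, w, v and mex1). Fewer are named in the text.

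The alternatives tried were scaling by relative log expression, TMM factors computed without the 100 most abundant genes, DESeq2 1.42.0, no expression filter, a minimum count of 50, a fit of only the groups compared, dispersion without robust estimation, a replicate block, leaving out each library in turn, an adjusted p under 0.01, and an added log2 change of at least 1. Leaving out each library for the counts of changed list members was added after the data were seen. The effect along the sex difference was compared with 40 simulated data sets, and the other splits of the libraries into groups of 3 were counted. The gene-level test was tested on simulated data with 200 changed genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

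Total counts ran from 36212113 to 45068874 per library, with a median of 638 counts per tested gene and library, and 971 tested genes had a median count under 20. In the simulations a log2 change of 1 was recovered for 70% of changed genes in the female dsxRNAi contrast (9580 genes), 62% in the male one (9582 genes), 82% in the sex contrast of controls (9572 genes), 70% in the sex contrast under dsxRNAi (9581 genes) and 66% in the interaction (9594 genes). For a log2 change of 0.5 the shares were 32%, 30%, 26%, 32% and 6%. False calls made up 3.29%, 2.78%, 6.79%, 8.23% and 4.03% of the calls. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. A gene at 0 in all libraries of a group kept a level of 0 CPM, and its log2 change came from the fit with the prior count of 0.125.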

Results

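Gene expression was measured by RNA sequencing in midguts of adult virgin flies in which dsx, the gene for the sex-specific transcription factors of somatic sex determination, was targeted by RNA interference (dsxRNAi) in enterocytes, the absorptive cells of the gut. The driver, mex1-Gal4, was silenced by a temperature-sensitive Gal80 during 6 days at 18 degrees C and released during 4 days at 29 degrees C, and the flies were sampled at day 10. Control flies carried the same driver with UAS-GFP. By its title the series concerns Myc and the regional and sexually dimorphic control of gut lipids, and its design asks what dsxRNAi does to the midgut of each sex. Each combination of sex and genotype had 3 libraries, 12 in all. The total count per library ran from 40389954 to 42214921 in control females, from 39137615 to 42425002 in dsxRNAi females, from 39898426 to 41794835 in control males and from 36212113 to 45068874 in dsxRNAi males. The 10 most abundant genes took 16.8 ± 1.46%, 17.9 ± 0.482%, 17.0 ± 0.482% and 20.7 ± 0.332% of the counts in the same groups (SD, n = 3).

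Libraries grouped by sex and genotype. The first principal component of the log2 expression values held 27.6% of the variance and the second 24.4%, and the 4 groups lay apart on them. Replicates of a group differed by more than counting noise, with Pearson correlations across genes of 0.987 to 0.997 between their log2 values (genes are not independent replicates). All gene positions given are on build dm6, and all levels are normalised CPM, mean ± SD of 3 libraries. Genes were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test. For each gene given as called in a contrast of a pair of groups, the 3 libraries of 1 group all lay above the 3 of the other. This adds little to the call itself, since it held for 99% to 100% of the called genes. It held for 17% to 38.6% of all tested genes, depending on the contrast, where chance gives 10%.

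**Figure D1:**
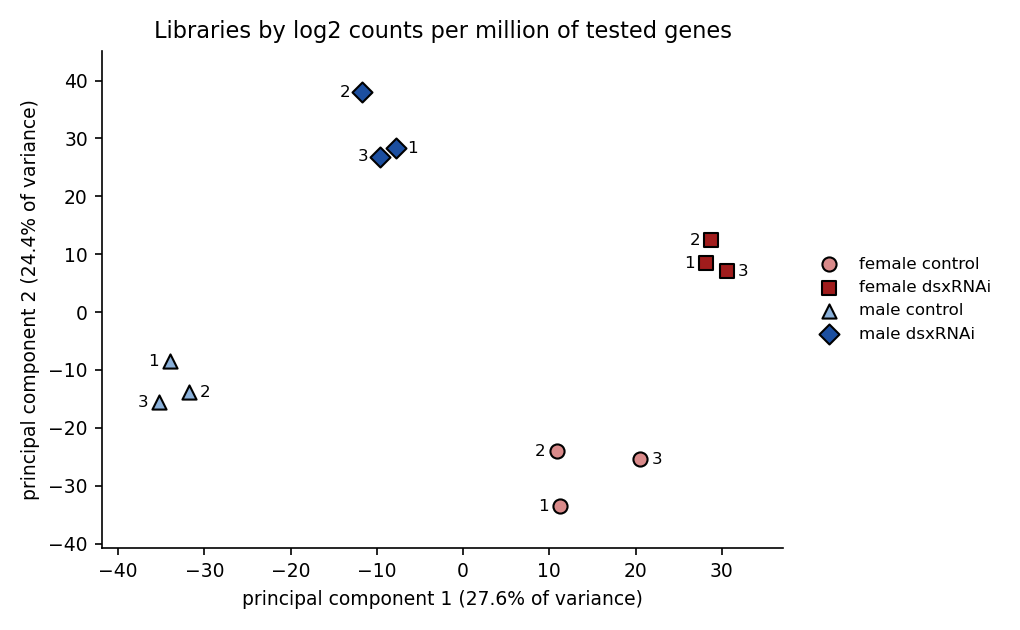
Principal components of log2 expression, with 1 point per library, coloured by group and marked by replicate number; the axes give the share of variance. The 4 groups of 3 libraries occupy separate places.

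The target of the RNA interference was lower in dsxRNAi males than in control males, and no fall was detectable in females. dsx (chromosome 3R, 7924323 to 7967408) stood at 70.1, 59.1 and 53.2 CPM in the 3 control male libraries and at 35.2, 43.1 and 41.2 CPM in the dsxRNAi male libraries. Its mean fell by 34.5%, from 60.8 ± 8.58 to 39.8 ± 4.14 CPM. The log2 change in males was -0.61 with a 95% interval of -0.88 to -0.34 (adjusted p = 0.00643), and the exact permutation test gave p = 0.1, the smallest possible here. In females the 3 control libraries held 18.6, 20.3 and 21.3 CPM and the dsxRNAi libraries 16.5, 22.3 and 19.9 CPM. The female log2 change was -0.04 with a 95% interval of -0.31 to 0.24 (adjusted p = 0.946, exact permutation p = 0.8). The female and male effects on dsx differed by 0.57 on the log2 scale without passing the threshold (adjusted p = 0.172). Control males held 3.03-fold more dsx transcript than control females (log2 female minus male -1.60, adjusted p = 1.57e-05). The counts sum all dsx isoforms over all cells of the midgut, and reads from the interference hairpin itself cannot be separated from those of the gene. The driver gene mex1, an enterocyte marker (3L, 15517424 to 15519592), passed the threshold in neither sex (log2 -0.11, adjusted p = 0.737 in females; log2 0.33, adjusted p = 0.0516 in males).

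**Figure D2:**
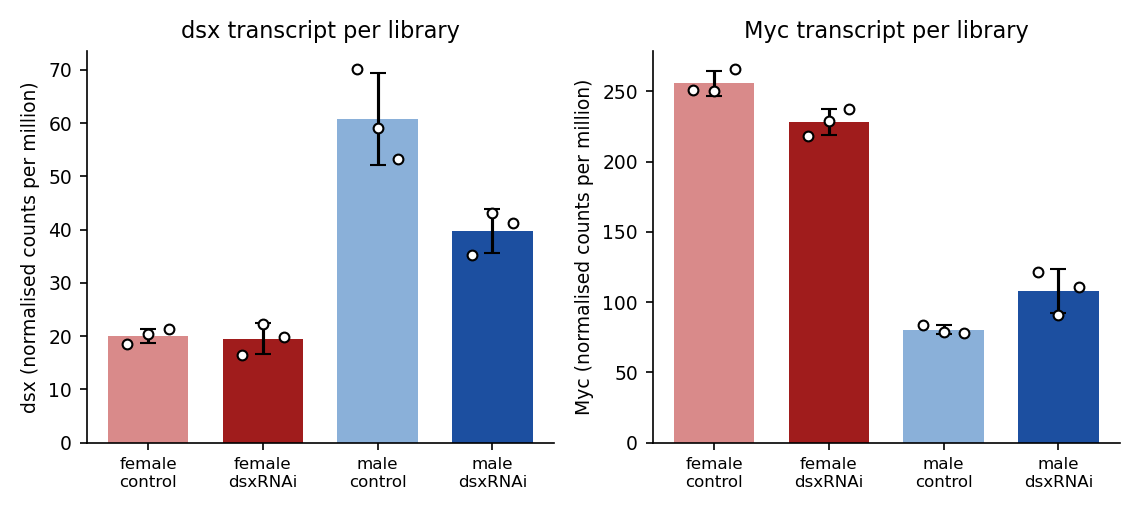
Normalised CPM of dsx and Myc, with 1 point per library and the mean and SD of each group of 3. dsx is highest in control males (60.8 ± 8.58) and Myc in control females (256 ± 8.64).

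Control female midguts held more Myc and more of nearly every ribosomal protein transcript than control male midguts, while some peptide hormone, detoxification and sugar-digesting enzyme genes were higher in control males. The contrast asks how the sexes differ before dsx is targeted. It called 1937 of 9686 genes (20%), 1039 higher in females and 898 lower, and 359 of them differed at least 2-fold. Myc, a transcription factor that drives ribosome production and growth (X, 3373159 to 3391697), stood at 256 ± 8.64 CPM in females and 80.3 ± 3.19 CPM in males (log2 1.67, adjusted p = 1.1e-06). Of 79 ribosomal protein genes 75 were called higher in females, 78 adjusted over the list alone, with a median log2 difference of 0.61 (camera adjusted p = 5.68e-56, but adjusted p = 0.27 with an estimated correlation). RpL14 of the large subunit (3L, 8601006 to 8602392) stood at 987 ± 98.8 CPM in females and 591 ± 12.2 CPM in males. The Myc network and ribosome biogenesis list had 18 of 22 genes higher, 19 adjusted over the list alone (camera adjusted p = 1.31e-14, adjusted p = 0.27 with an estimated correlation). Among them Nopp140, a nucleolar chaperone, was 1.77-fold higher (77.6 ± 4.29 against 43.9 ± 3.08 CPM, adjusted p = 0.000273), and bys, needed to assemble small ribosomal subunits, 1.85-fold higher (adjusted p = 0.000378).

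Some sex determination and dosage compensation genes separated the sexes in the direction that the sex labels give. roX1, a noncoding RNA of the male dosage compensation complex (X, 3857230 to 3862697), stood at 1239 ± 86.3 CPM in control males and 0.547 ± 0.0854 CPM in control females. msl-2, which assembles that complex (2L, 3462218 to 3466112), was 2.94-fold higher in males (31.2 ± 0.888 against 10.6 ± 2.02 CPM, adjusted p = 1.03e-05). Sxl, the switch gene of female development (X, 7074550 to 7098053), was 1.84-fold higher in females (adjusted p = 9.58e-05), and tra, its splicing target, 1.44-fold (adjusted p = 0.00277). In this list 2 genes were higher and 5 lower in females among 14, 2 and 6 adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.46 with an estimated correlation). Yp1, a yolk protein gene activated by the female dsx isoform in fat body, stood at 48.9 ± 4.43 CPM in control females and 0.0234 CPM in control males. The Yp genes made up the 3 called of 5 tested dsx targets (3 adjusted over the list alone).

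Genes higher in control males included gut hormones and sugar-digesting enzymes. Some markers of visceral muscle and neurons, given under other observations, were higher in control males too. Among digestive serine proteases and lysozymes, more of the called genes were higher in control females. By DESeq2, 8 of 29 proteases were higher and 2 lower in control females, and 3 of 6 lysozymes were higher and 0 lower. The protease gene Jon65Aii stood at 1110 ± 233 CPM in control females and 498 ± 73 CPM in control males. Of 19 enteroendocrine cell genes 13 were lower in females, 14 adjusted over the list alone, and 1 was higher, 1 adjusted over the list alone, with 0 without control female 3, control male 2 or control male 3 (camera adjusted p = 1.19e-07, adjusted p = 0.122 with an estimated correlation). The peptide hormone genes AstA (3R, 24760530 to 24765071; 30.5 ± 0.854 CPM in females, 48.3 ± 5.17 CPM in males, adjusted p = 0.000236) and Tk (3R, 11994175 to 12005473; 78.1 ± 9.11 and 117 ± 6.10 CPM, adjusted p = 0.00117) were among them. The list of starch and sugar digestion also holds lysosomal alpha-mannosidases. Of its 20 genes 8 were lower in females, 11 adjusted over the list alone, and 5 were lower without control female 3, without control male 1 or without control male 2 (camera adjusted p = 4.58e-05, adjusted p = 0.299 with an estimated correlation). The maltase Mal-A2 (2R, 8453627 to 8455782) stood at 798 ± 28.2 CPM in females and 1294 ± 42.7 CPM in males. Among 33 detoxification enzymes 11 were lower in females, 13 adjusted over the list alone, with 5 without control female 3, 6 without control male 1 and 6 without control male 3 (camera adjusted p = 1.19e-07, adjusted p = 0.122 with an estimated correlation). Cyp6g1, a P450 of insecticide resistance (2R, 12185667 to 12188431), was 1.96-fold lower (413 ± 38.6 against 809 ± 29.5 CPM, adjusted p = 0.00674), and ImpL3, lactate dehydrogenase (3L, 6259105 to 6262694), 1.84-fold lower (adjusted p = 0.000283).

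Some lipid genes differed between the sexes, in both directions. In the lipid digestion and transport list 5 of 24 genes were higher in females and 8 lower, the same numbers adjusted over the list alone, and its median (-0.05), its mean (0.07) and camera's direction (down, adjusted p = 0.874) differed in sign. The number lower was 4 without control female 1, 5 without control female 2, 4 without control female 3 and 3 without control male 1. Npc1b, required for sterol uptake in the gut (X, 20934869 to 20939503), was 2.54-fold higher in females (308 ± 87.2 against 121 ± 14.1 CPM, adjusted p = 0.00404). The lipase gene CG31091 (3R, 25899903 to 25902172) was 3.63-fold lower in females (84.8 ± 9.13 against 308 ± 21.4 CPM, adjusted p = 0.0012). Desat1, a fatty acid desaturase (3R, 12439600 to 12447616), was 1.44-fold higher in females (433 ± 53.7 against 300.3 ± 35.0 CPM, adjusted p = 0.00553). In its list, lipid synthesis and storage, 2 of 22 genes were higher and 3 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.509), with 1 higher without control female 3 or control male 1 and 1 lower without control female 1, control female 3 or control male 1. srl, a coactivator of mitochondrial and Myc target genes (3R, 4422483 to 4429335), was 2.05-fold higher (36.3 ± 0.894 against 17.7 ± 2.11 CPM, adjusted p = 0.000446). Control male library 1 also carried 8031 counts of male accessory gland genes, against 4 to 18 in the other 11 libraries.

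Some digestive enzyme, lysozyme, lipid-handling and respiratory chain genes rose in dsxRNAi males, and some gut hormone and detoxification genes fell. The contrast asks what dsxRNAi does to the male gut, though stock and dsxRNAi vary together. It called 1418 genes (14.6%), 780 higher and 638 lower, and 346 of them changed at least 2-fold. The count was 856 without control male 2 and 921 without control male 3. Of 29 digestive serine proteases 15 rose, 18 adjusted over the list alone, where 1 was lower (camera adjusted p = 1.9e-15, adjusted p = 0.12 with an estimated correlation). Jon25Bi (2L, 4954279 to 4955144) went from 649 ± 77.2 to 4494 ± 1040 CPM, a 6.92-fold rise (adjusted p = 0.000909). Of 6 digestive lysozymes, which break down bacterial cell walls, 4 rose and 1 fell, the same numbers adjusted over the list alone, and the fall was not called without dsxRNAi male 1, 2 or 3 or control male 3 (camera adjusted p = 4.68e-08, adjusted p = 0.0703 with an estimated correlation). LysB (3L, 1207371 to 1207981) rose 4.45-fold from 12.8 ± 2.30 to 57.0 ± 17.1 CPM (adjusted p = 0.000168), and reads of its near-identical neighbours may be split between copies. PGRP-SC1a, an amidase that degrades peptidoglycan (2R, 8709733 to 8710320), rose 17.9-fold from 12.7 ± 1.82 to 228 ± 110 CPM (adjusted p = 3.91e-05), with the same uncertainty toward its copy PGRP-SC1b.

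Lipid genes were among the male changes. In the lipid digestion and transport list 7 of 24 genes rose and 1 fell, 8 and 1 adjusted over the list alone, and the list was called with the preset correlation (camera adjusted p = 2.89e-09) and with an estimated correlation (adjusted p = 0.00386). The lipase gene CG17192 (3R, 27017180 to 27018287) rose 6.97-fold from 194 ± 53.7 to 1356 ± 34.8 CPM (adjusted p = 0.00011). Its neighbour CG6295 (3R, 27005899 to 27007055) rose 2.35-fold from 1913 ± 352 to 4504 ± 584 CPM (adjusted p = 0.00139). Lsd-1, a lipid droplet coat protein (3R, 23763857 to 23766662), rose 3.60-fold from 13.0 ± 4.25 to 46.7 ± 10.7 CPM (adjusted p = 0.0049). bmm, a triglyceride lipase gene (3L, 14776496 to 14786412), rose 2.26-fold from 85.0 ± 16.6 to 192 ± 16.4 CPM (adjusted p = 0.00402). It was called higher in dsxRNAi females too, so its rise is not particular to males. Lip4 and CG17191 of the lipid digestion and transport list were also called in females. In the list of lipolysis and fatty acid oxidation 5 of 17 genes rose, 7 adjusted over the list alone, with 3 without control male 1, 3 without control male 2 and 3 without control male 3 (camera adjusted p = 0.00166, adjusted p = 0.195 with an estimated correlation). In the list of lipid synthesis and storage 4 of 22 genes rose, 4 adjusted over the list alone, with 2 without dsxRNAi male 2, 2 without control male 2 and 2 without control male 3 (camera adjusted p = 0.174).

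Some growth and energy genes rose in dsxRNAi males by small amounts, and none of their 3 lists was called with an estimated correlation. All 60 tested genes of the respiratory chain and ATP synthase had a log2 change above 0, with a median of 0.34, and 36 were called, 54 adjusted over the list alone. That number was 22 without dsxRNAi male 1, 23 without dsxRNAi male 2, 15 without control male 2 and 19 without control male 3 (camera adjusted p = 4.49e-18, adjusted p = 0.113 with an estimated correlation). ND-13B of complex I (3L, 10693184 to 10694108) rose 1.57-fold from 37.0 ± 1.21 to 58.2 ± 3.60 CPM (adjusted p = 0.000284). Myc rose 1.34-fold from 80.3 ± 3.19 to 108 ± 15.7 CPM (log2 0.43, adjusted p = 0.0106). Of 79 ribosomal protein genes 78 had a log2 change above 0 (median 0.29) and 24 were called, 44 adjusted over the list alone, with 7 without dsxRNAi male 1, 10 without control male 1, 6 without control male 2 and 7 without control male 3 (camera adjusted p = 1e-10, adjusted p = 0.669 with an estimated correlation). The Myc network and ribosome biogenesis list had 8 of 22 called, 14 adjusted over the list alone, a number that was 1, 15 and 1 without dsxRNAi males 1, 2 and 3 and 3, 1 and 1 without control males 1, 2 and 3 (camera adjusted p = 0.00103, adjusted p = 0.693 with an estimated correlation).

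Genes that fell in dsxRNAi males included hormones, P450 enzymes and 4 of 14 heat shock genes, all Hsp70 copies (4 adjusted over the list alone, camera adjusted p = 0.159). Of 19 enteroendocrine genes 8 fell, 10 adjusted over the list alone, with 4 without dsxRNAi male 2, 5 without dsxRNAi male 3, 4 without control male 1, 5 without control male 2 and 5 without control male 3 (camera adjusted p = 1.31e-05, adjusted p = 0.12 with an estimated correlation). AstA fell from 48.3 ± 5.17 to 30.5 ± 2.22 CPM (log2 -0.66, adjusted p = 0.000195), close to its level in control females. Some markers of other cells fell too, with 2 of 15 for visceral muscle, 2 adjusted over the list alone and 1 without control male 3 (camera adjusted p = 0.0335, adjusted p = 0.693 with an estimated correlation), and 1 of 5 for neurons, elav, 3 adjusted over the list alone (camera adjusted p = 0.165). Malpighian tubules had 1 of 5, NtR, 1 adjusted over the list alone, with 0 without dsxRNAi male 1, dsxRNAi male 2 or control male 3 (camera adjusted p = 0.944), and progenitor cells 2 of 10, 3 adjusted over the list alone, with 0 without dsxRNAi male 1 or control male 3 and 1 without dsxRNAi male 2, control male 1 or control male 2 (camera adjusted p = 0.121). Of 33 detoxification genes 11 fell and 2 rose, 13 and 2 adjusted over the list alone, and 1 rose without dsxRNAi male 1, control male 2 or control male 3 (camera adjusted p = 0.0045, adjusted p = 0.288 with an estimated correlation), and the P450 gene Cyp6a2 (2R, 6779749 to 6781491) fell 8.77-fold from 78.3 ± 7.28 to 8.95 ± 3.33 CPM (adjusted p = 0.000282). The male comparison includes the control library with accessory gland transcripts. The dsxRNAi and control genotypes carry different autosomes by their labels, so stock and dsxRNAi vary together.

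Fewer genes were called between dsxRNAi and control females than in males, and those given below are single genes of differing function. Larger fitted changes included CG32302, which fell 43.9-fold, and Drsl2, which rose 14.0-fold. Stock and dsxRNAi vary together in females too, and no fall of dsx was detectable there, so the calls cannot be assigned to dsxRNAi alone. The contrast called 335 genes (3.46%), 185 higher and 150 lower, and 169 of them changed at least 2-fold. The count was 204 without dsxRNAi female 2 and 214 without control female 3. Cyp6w1, a P450 gene (2R, 6173684 to 6176195), fell 25.7-fold from 20.1 ± 7.44 to 0.777 ± 0.364 CPM (log2 -4.68, adjusted p = 1.91e-05). CG15169 (2L, 18991020 to 18992409), of no assigned function here, fell 8.32-fold from 15.0 ± 3.09 to 1.80 ± 0.418 CPM (adjusted p = 8.58e-07). CG7227, a scavenger receptor gene of the CD36 family (2L, 7994388 to 7998151), rose 10.4-fold from 1.66 ± 0.294 to 17.4 ± 4.25 CPM (adjusted p = 1.9e-06). danr, a transcription factor of antennal and eye development (3R, 25138072 to 25139903), rose 5.18-fold from 0.694 ± 0.0972 to 3.61 ± 0.308 CPM (adjusted p = 4.25e-05). Ilp3, an insulin-like peptide made in gut muscle and brain (3L, 9801298 to 9802120), stood at 0.0167 CPM in control females and 1.31 ± 0.112 CPM in dsxRNAi females (adjusted p = 0.000153), and at 0.00772 and 0.507 ± 0.0606 CPM in the male groups.

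Some heat shock, detoxification and protease genes were called in females, and none of their 3 lists was called with an estimated correlation. Of 14 heat shock genes 4 fell, 4 adjusted over the list alone, where 1 was higher (camera adjusted p = 0.0196, adjusted p = 0.945 with an estimated correlation). The 4 are Hsp70 copies, among which reads may be split, and Hsp70Bb (3R, 12505793 to 12508139) fell 3.25-fold from 326 ± 32.1 to 100.2 ± 9.57 CPM (adjusted p = 1.9e-06). Of 33 detoxification genes 6 fell and 1 rose, 11 and 1 adjusted over the list alone, and 3 fell without dsxRNAi female 3 (camera adjusted p = 0.00207, adjusted p = 0.565 with an estimated correlation). Of 29 serine proteases 2 rose, 6 adjusted over the list alone, where 1 was lower, with 1 without dsxRNAi female 2, 5 without control female 2 and 1 without control female 3 (camera adjusted p = 3.6e-07, adjusted p = 0.565 with an estimated correlation), and iotaTry, a trypsin (2R, 11356720 to 11357537), rose 1.47-fold from 130 ± 14.7 to 190 ± 7.47 CPM (adjusted p = 0.00349). edgeR called 0 of the 79 ribosomal protein genes, with 4 lower at an unadjusted p under 0.05 and 0 by DESeq2, although 77 of them lay below 0 (median log2 -0.11, camera adjusted p = 1.48e-10, adjusted p = 0.945 with an estimated correlation).

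Of the yolk protein genes Yp2 and Yp3 were called lower in dsxRNAi females, with a wide spread between libraries, and Yp1 was not called (48.9 ± 4.43 to 16.4 ± 11.6 CPM, log2 -1.57, adjusted p = 0.0741). Yp3 (X, 13759546 to 13761547) stood at 26.1 ± 19.4 CPM in control females and 4.57 ± 1.41 CPM in dsxRNAi females (log2 -2.51, adjusted p = 0.025), and its call ended without dsxRNAi female 1, 2 or 3 (adjusted p = 0.0595, 0.114 and 0.1). Yp2 (X, 10050951 to 10052636) went from 20.3 ± 12.7 to 4.50 ± 2.54 CPM (log2 -2.17, adjusted p = 0.0431), and its call ended without dsxRNAi female 2 or 3 or control female 1 (adjusted p = 0.167, 0.154 and 0.0823). These made 2 of 5 dsx targets called, 3 adjusted over the list alone, with 0 without dsxRNAi female 2 or 3 and 1 without control female 1. Markers of fat body, where yolk proteins are made, and of hemocytes had a median log2 change of -0.86 with 8 of 8 below 0, although Ppn (-0.11) and Pxn (-0.10) hardly differed. edgeR called 0 of these 8, with 2 at an unadjusted p under 0.05 and 0 by DESeq2.

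**Figure D3:**
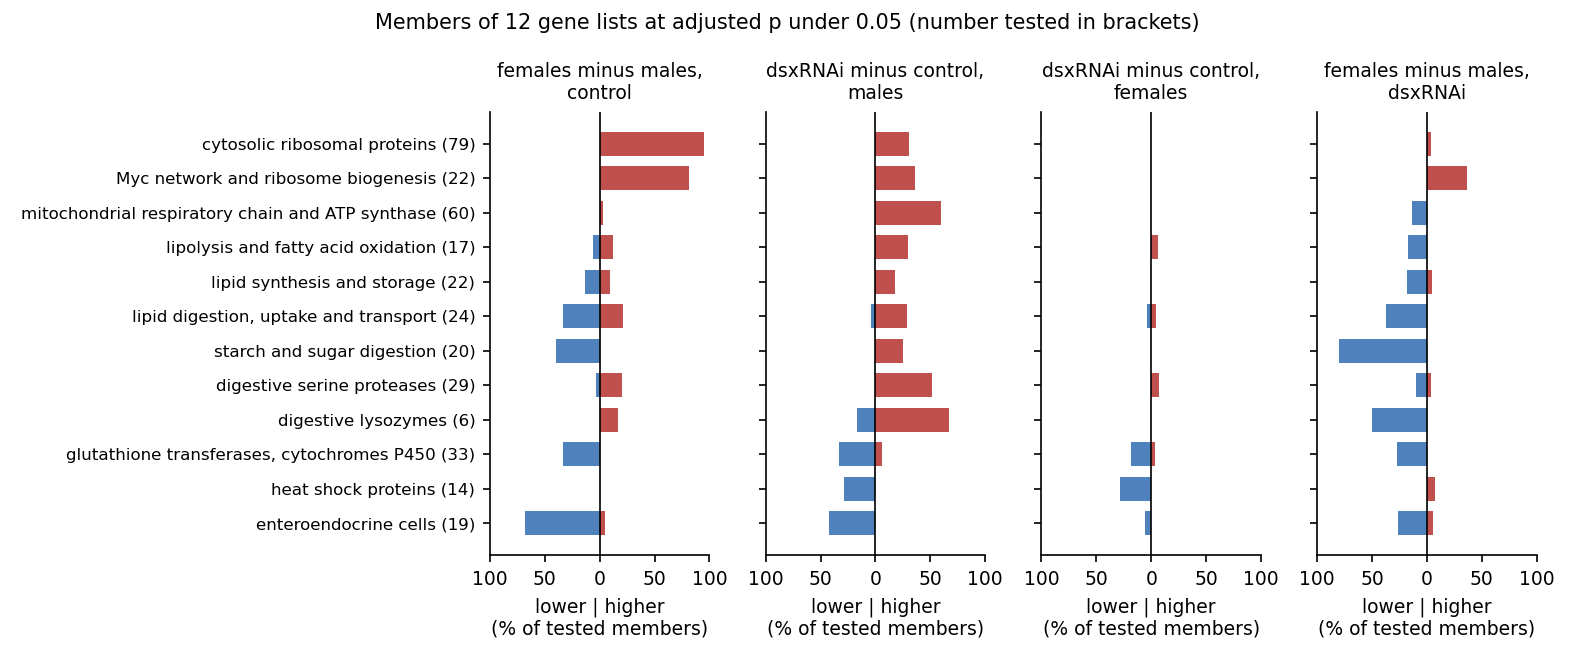
Percentage of tested genes called higher (right) or lower (left) in 12 of the gene lists, for 4 contrasts. In control females 75 of 79 ribosomal protein genes are higher than in control males, and under dsxRNAi in males 36 of 60 respiratory chain genes are higher than in controls.

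Many genes changed the same way under dsxRNAi in both sexes. Of the 335 female and 1418 male calls, 252 were shared and 247 of these had the same direction. There were 146 genes higher in both sexes against 14.9 expected if the calls were independent, and the genes lower in both sexes also exceeded their expected 9.88. The number shared in direction was 162 without dsxRNAi female 2. The contrasts have no library in common. Over all genes the correlation of the female and male log2 changes was 0.242 (Spearman 0.375), across genes that are not independent replicates. Cyp6w1, CG15169, CG7227 and Hsp70Bb were in this set, and in males they changed 43.5-fold down, 9.85-fold down, 27.5-fold up and 4.67-fold down (adjusted p = 7.08e-06, 1.64e-07, 1.64e-07 and 1.64e-07). nrv3, a sodium pump subunit of enteroendocrine cells (2L, 21380000 to 21393319, in a region where 27 of 208 tested genes were shared calls), fell in both sexes, from 85.2 ± 12.7 to 40.3 ± 3.20 CPM in females and from 99.6 ± 19.6 to 35.6 ± 3.65 CPM in males.

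The shared genes lay on the autosomes far more often than on the X chromosome, which has the same label in both genotypes. On the X 6 of 1590 tested genes were shared calls (0.377%), against 237 of 7808 on the autosomes (3.04%), an odds ratio of 0.121 with a 95% interval of 0.0439 to 0.268 (Fisher's exact test, two-sided, p = 5.5e-13). Male calls outside the shared set were less uneven, with 165 on the X and 974 on the autosomes (odds ratio 0.812, interval 0.678 to 0.969). Sex differences in controls went the other way, with 486 of 1590 X-linked genes called (30.6%), 320 of them higher in females. Fisher's test treats genes as independent. Shared calls lay near one another more often than in random draws, as given below. The interval for the shared calls may therefore be too narrow and its p too small.

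**Figure D4:**
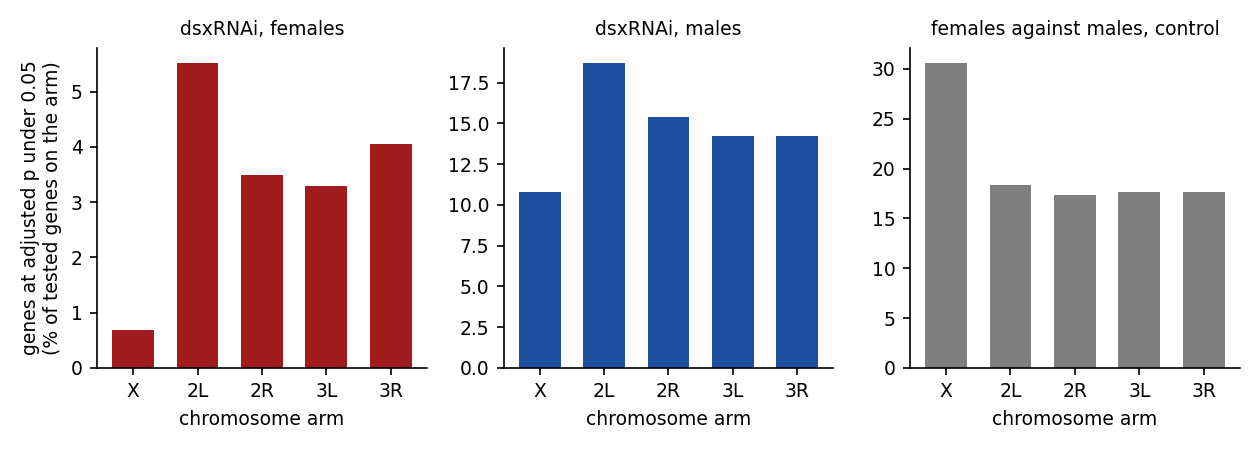
Percentage of tested genes called on each large chromosome arm in 3 contrasts, each panel on its own scale from 0. Under dsxRNAi in females 0.692% of X-linked genes are called and 3.29% to 5.52% of those on the 4 large autosome arms, while the sex contrast of controls calls 30.6% on the X.

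The genes that differ between control males and females were compared with the effect of dsxRNAi. Among genes with a sex difference in controls, those higher in females had a median log2 change of 0.19 under dsxRNAi in males. Those higher in males had -0.17, a difference of 0.36. Of 100 splits of the libraries 5, the real one included, reached it. All 5 keep the male groups whole, so these splits do not decide whether chance gave the difference. The highest with the male groups mixed was 0.323. Because the control male libraries enter both contrasts, simulated unchanged groups gave a mean of 0.127 (0.104 to 0.149 over the simulations). Taking sex bias from both genotypes removes the part that shared control libraries give by chance, though the libraries are still shared. The male difference was then 0.07, against -0.02 to 0.01 in the simulations. Genes higher in females had a median of 0.04 there, while those higher in males (-0.0232) lay level with the other genes (-0.0245). In females the difference was -0.11, within the simulated range of -0.14 to -0.10, and with sex bias from both genotypes -0.04, below the simulated -0.02 to 0.01. Without control female 2 the female difference was -0.22. The simulations treat genes as independent and hold no dsxRNAi effect. A real dsxRNAi effect enters the sex bias taken from both genotypes and pulls that difference away from the other sex. How far it does so is not shown by the simulations. The fall from 0.36 to 0.07 in males need not be removal of chance alone.

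Under dsxRNAi the sexes lay apart in many genes, and some lipid-digesting and most sugar-digesting enzymes were lower in females. The contrast asks which sex differences are present when dsx is targeted in enterocytes. It called 1436 genes (14.8%), 752 higher in females and 684 lower, with 637 without dsxRNAi female 3 and 671 without dsxRNAi male 2. Neither direction prevailed in every setting, since 647 of 1357 calls were higher in females with scaling by relative log expression, 656 of 1423 at a minimum count of 50, 850 of 1782 by DESeq2 and 498 of 1039 in a fit of the 2 groups alone. Of 20 starch- and sugar-digesting enzymes 16 were lower in females, 18 adjusted over the list alone, and 8 without dsxRNAi female 3 (camera adjusted p = 4.32e-17, adjusted p = 0.1 with an estimated correlation). LManIII, a lysosomal alpha-mannosidase (2L, 8765273 to 8768710), stood at 414 ± 147 CPM in females and 1777 ± 523 CPM in males (adjusted p = 0.00422). Several such mannosidases are in this list, so its counts are not of digestive enzymes alone. Amy-p, an amylase gene whose reads may be shared with its copy Amy-d (2R, 17118636 to 17120303), was 1.77-fold lower in females (adjusted p = 0.00705). In the lipid digestion and transport list 9 of 24 genes were lower, 12 adjusted over the list alone, and the list was called with both correlations (camera adjusted p = 1.17e-09, adjusted p = 0.00315 with an estimated correlation). The lipase gene CG31091 was 5.04-fold lower in females (98.2 ± 11.8 against 495 ± 247 CPM, adjusted p = 0.000786).

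Myc differed by sex under dsxRNAi as well. Myc stood at 228 ± 9.41 CPM in dsxRNAi females and 108 ± 15.7 CPM in dsxRNAi males (log2 1.08, adjusted p = 6.66e-05). Its change under dsxRNAi differed between the sexes by -0.59 without passing the threshold (adjusted p = 0.0704). Of 79 ribosomal protein genes 3 were higher in females, 1 adjusted over the list alone, with 1 without each of dsxRNAi females 1, 2 and 3 and dsxRNAi males 2 and 3, and 5 without dsxRNAi male 1 (median log2 0.21, camera adjusted p = 2.76e-16, adjusted p = 0.392 with an estimated correlation). Sxl was 2.12-fold higher in females (adjusted p = 4.47e-05), msl-2 3.06-fold higher in males (adjusted p = 1.05e-05), and dsx stayed higher in males (log2 -1.03, adjusted p = 0.000571). The respiratory chain list had 8 of 60 lower in females, 8 adjusted over the list alone, with 2 without dsxRNAi female 3, 5 without dsxRNAi male 1 and 3 without dsxRNAi male 2 (camera adjusted p = 6.76e-05, adjusted p = 0.392 with an estimated correlation). Dh31, a gut hormone that acts on muscle contraction (2L, 8491868 to 8506845), was 1.72-fold lower in females (10.2 ± 1.04 against 17.5 ± 2.74 CPM, adjusted p = 0.00104). In its list of 19 enteroendocrine genes 5 were lower and 1 higher, the same numbers adjusted over the list alone, with 2 lower without dsxRNAi female 3 (camera adjusted p = 0.0456, adjusted p = 0.392 with an estimated correlation).

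The effect of dsxRNAi differed between the sexes for a small set of genes, 53 of them with the more positive effect in males. The interaction asks this question gene by gene, as the female effect minus the male effect. It called 78 genes (0.805%), 25 positive and 53 negative, a number that leaving out most of the libraries moved. It was 44 and 33 without dsxRNAi females 1 and 3, 119 and 35 without control females 1 and 3, 45 and 127 without dsxRNAi males 1 and 2, and 45, 34 and 36 without control males 1, 2 and 3. PGRP-SC1a had the interaction -3.92 (adjusted p = 0.00308), with 18.7 ± 0.376 and 22.2 ± 3.52 CPM in control and dsxRNAi females and 12.7 ± 1.82 and 228 ± 110 CPM in the male groups. CG15263 (2L, 15285000 to 15286047) had the interaction 2.27 (adjusted p = 0.00862), with 223 ± 64.8 and 254 ± 14.4 CPM in females and a drop from 1381 ± 111 to 326 ± 107 CPM in males. Zip42C.2, a zinc transporter (2R, 6718196 to 6719533), went from 27.4 ± 6.67 to 8.55 ± 2.09 CPM in females and from 2.35 ± 0.739 to 6.34 ± 0.807 CPM in males (interaction -3.11, adjusted p = 0.00311). CG10178, a UDP-glycosyltransferase gene (2L, 18509560 to 18513512), fell in males from 29.3 ± 0.720 to 11.1 ± 0.914 CPM and stood at 14.3 ± 0.450 and 13.4 ± 1.39 CPM in females (interaction 1.30, adjusted p = 0.00132).

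Some lipid-digesting enzymes and lysozymes differed between the sexes in their response. The interaction called 11 lists with the preset correlation, a number that 34 of 100 splits of the libraries reached. Lipid digestion and transport had 2 of 24 genes called, both with the more positive effect in males, 6 adjusted over the list alone, and the list was called with the preset correlation (camera adjusted p = 1.02e-09) and with an estimated correlation (adjusted p = 0.00308). The number called was 2 or more only without control female 1, was 1 without dsxRNAi female 2, control female 2, dsxRNAi male 1 or dsxRNAi male 2, and was 0 without any of the other 7 libraries. The lysozymes had 2 of 6 called in the same direction, 5 adjusted over the list alone (camera adjusted p = 5.6e-09, adjusted p = 0.0429 with an estimated correlation). Their number was 1 without control female 1, dsxRNAi male 3 or control male 1, and 0 without dsxRNAi female 1 or 3, control female 2 or 3, dsxRNAi male 1 or control male 2 or 3. Of 79 ribosomal protein genes 1 was called, 45 adjusted over the list alone, with a median of -0.40, and the number was 14 without control female 1, 4 without dsxRNAi male 2 and 0 without dsxRNAi female 1 or 3, control female 3 or control male 1, 2 or 3 (camera adjusted p = 1.22e-34, adjusted p = 0.319 with an estimated correlation). edgeR called 0 of the 60 respiratory chain genes, with 35 negative at an unadjusted p under 0.05, 3 by DESeq2 and 13 adjusted over the list alone (camera adjusted p = 7.38e-18, adjusted p = 0.122 with an estimated correlation). edgeR called 0 of 22 genes of the Myc network and ribosome biogenesis, with 15 negative at an unadjusted p under 0.05, 7 by DESeq2 and 14 adjusted over the list alone (camera adjusted p = 4.47e-09, adjusted p = 0.393 with an estimated correlation).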

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

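The tests of an autosomal strain background, of clustering without 1 region, of a loss of dsx transcript, of a single library in the second pattern, of a larger share of enterocytes and of less fat body tissue were chosen after the result was seen.

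The effect of dsxRNAi differed between females and males, by a test of the difference itself, for 78 genes. Of 100 drawn splits of the libraries within each sex 4, the real one included, gave as many genes, and the highest of the other splits gave 773. All 4 keep the male groups whole, as 6 of the 100 splits do, and the highest count with the male groups mixed was 4. This points to a structure of the samples in which the contrast between the male groups is strong, so these splits do not decide whether chance gave the 78. For lists, 34 of 100 splits gave as many as the real 11, with 16 as the highest other, so chance cannot be excluded there.

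The named genes with such a difference, given as the female log2 change minus the male one, were higher for CG15263 (2.27), Rph (1.93), danr (1.79), CG10178 (1.30), CG5171 (1.28) and CG13117 (1.28). They were lower for CG4563 (-4.82), PGRP-SC1a (-3.92), PGRP-SC1b (-3.52), CG16775 (-3.14), Zip42C.2 (-3.11), CG4991 (-2.82), the lipase genes CG6296 (-1.24) and CG17192 (-1.93), the protease gene Jon65Aii (-1.11), the lysozymes LysE (-1.98) and LysB (-1.68) and the ribosomal protein gene RpS15Ab (-0.54). With each library left out in turn CG15263, CG10178, CG4563, PGRP-SC1a, PGRP-SC1b and Zip42C.2 stayed past the threshold. The calls of danr ended without dsxRNAi female 3, control female 3, dsxRNAi male 1, control male 2 and control male 3 (adjusted p up to 0.0574), and those of RpS15Ab without dsxRNAi females 1 and 3, control female 3 and each control male (up to 0.0787).

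Rph lost its call without any library except control female 1 and dsxRNAi males 2 and 3 (adjusted p up to 0.0943). The libraries whose removal left the call in place were dsxRNAi female 3, control females 1 and 2 and dsxRNAi male 2 for CG5171 (otherwise up to 0.089), and dsxRNAi female 1, control females 1 and 2 and control male 1 for CG13117 (up to 0.103). They were control female 2, dsxRNAi male 3 and control male 3 for CG16775 (up to 0.131), and dsxRNAi female 2, control female 1 and dsxRNAi male 2 for CG4991 (up to 0.136). CG6296 kept its call only without dsxRNAi female 2, control females 1 and 2 and dsxRNAi males 1 and 2 (otherwise up to 0.0943), and CG17192 only without control female 1 (up to 0.118). Jon65Aii kept it without control females 1 and 2, dsxRNAi males 2 and 3 and control male 1 (otherwise up to 0.103), LysE without dsxRNAi female 2, control female 1, dsxRNAi male 2 and control male 1 (up to 0.103), and LysB without dsxRNAi female 2 and dsxRNAi males 2 and 3 (up to 0.103).

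A signal in genes outside the comparisons was the male accessory gland list, of which no gene passed the expression filter. Control male 1 held 8031 counts of these genes (from 18 genes), against 4 to 18 counts in the other 11 libraries. Acp36DE with 1928 counts and Acp32CD with 1731 counts were the most abundant, both genes of seminal fluid proteins. No biological explanation was tested.

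The first pattern weighed is that 247 genes were called in the same direction under dsxRNAi in both sexes, while only 6 of 1590 X-linked genes were among them. Of 100 splits 1, the real one, gave as many shared calls, and the highest other gave 0. Splits that mix the groups called almost no genes in females, so these splits do not decide, while 146 genes were higher in both sexes against 14.9 expected if the calls were independent. A difference between the autosomes of the dsxRNAi and control stocks would give such an odds ratio, 0.121 (95% interval 0.0439 to 0.268). The labels give the same X to both stocks. That interval treats genes as independent and may be too narrow. Of the 237 shared autosomal genes 108 lay within 50 kb of another, against a median of 77 and a 95th percentile of 92 in 10000 random draws. Blocks of differing haplotype could give this excess. Neighbouring copies such as the Hsp70 genes, called lower in both sexes, can add to it, since the draws took single genes. The region from 20 to 22 Mb on 2L held 27 shared calls among 208 tested genes, and without it 84 of 210 lay within 50 kb of another, against a 95th percentile of 73. An effect of dsx loss in enterocytes of both sexes stays open, because the change of dsx itself in females was -0.0377 with an interval of -0.31 to 0.24, and the 2 cannot be told apart without controls from the same stock. A strain background may therefore account for part of the shared changes, as a hypothesis.

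The second pattern weighed is the median change of sex-biased genes toward the female control level in dsxRNAi males, a difference of 0.359 against a mean of 0.127 in simulated unchanged groups. With sex bias taken from both genotypes it was 0.0678, and only the genes higher in females (median 0.0446) stood apart. Those higher in males (-0.0232) lay level with the other genes (-0.0245). A real dsxRNAi effect in males lowers the difference taken this way, so the fall to 0.0678 need not be removal of chance alone. Against control libraries shared by both contrasts as the whole cause, the covariance with no shared library was 0.0763 at its lowest over 3 rotations, against 0.121 with all libraries. Against a single library, the mean of the rotations was 0.0907 and stayed between 0.0733 and 0.112 with any of the 9 libraries left out. A larger share of enterocytes stays open, because their 7 markers went both ways (mean log2 change 0.0135 ± 0.0774 (SE), from -0.25 to 0.33). Of 100 splits 5, the real one included, gave a difference as high, with 0.513 the highest other. All 5 keep the male groups whole, as 6 of the 100 splits do, and the highest with mixed groups was 0.323. These splits leave the contrast between the male groups intact, so they do not decide whether chance gave the difference. An effect of dsx on the male gut and a strain background may both still contribute.

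The third pattern weighed is the lower level of Yp2 and Yp3 transcripts in dsxRNAi females, while Yp1 was not called. The call of Yp3 ended without dsxRNAi female 1, 2 or 3, and that of Yp2 without dsxRNAi female 2 or 3 or control female 1. Less fat body tissue on the dissected midguts may explain it, since fat body and hemocyte markers had a median log2 change of -0.86 with 8 of 8 below 0. Among them apolpp, a fat body lipoprotein gene, stood at 8.66 ± 1.05 CPM in control females and 3.36 ± 1.22 CPM in dsxRNAi females, while Ppn, the most abundant at 79.0 ± 6.50 CPM in control females, and Pxn changed by -0.11 and -0.10, so the markers did not all move alike. Of 5 Malpighian tubule markers edgeR called 0, with 4 lower at an unadjusted p under 0.05, 2 by DESeq2 and 3 adjusted over the list alone, so less attached tissue of other kinds stays open too. A direct effect of dsx on these genes stays open, because the change of dsx in females was -0.0377, with an interval that includes both no change and a fall.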

How the results depend on the processing

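Leaving out each library for the counts of changed list members was chosen after the result was seen, and the other tests here were planned. Scaling by relative log expression, TMM factors without the 100 most abundant genes, no expression filter, a minimum count of 50 and dispersion without robust estimation kept every count of called genes within 1.5 times its value. The direction that prevailed among the calls for sex under dsxRNAi changed, with 52.4% higher in females here, 47.7% with scaling by relative log expression and 46.1% at a minimum count of 50. dsx in males kept its call in all of these and by DESeq2. Of the 308 calls of named genes 190 held in every setting, 55 ended only when a library was left out and 63 ended in another setting. Calls that ended were 15 of 29 for dsxRNAi in females, 22 of 82 in males and 24 of 89 for sex in controls. They were 45 of 90 for sex under dsxRNAi and 12 of 18 for the interaction.

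DESeq2 called 578 genes for dsxRNAi in females and 353 for the interaction, and the cause was not tested. A fit of only the compared groups, with fewer libraries to estimate dispersion, called 221 genes for dsxRNAi in females against 335 in the main fit. In males it called 1527 against 1418, and the cause was not tested. At an adjusted p under 0.01, stricter by construction, the counts were 160 for dsxRNAi in females, 670 in males, 1018 for sex in controls, 455 for sex under dsxRNAi and 22 for the interaction. With an added log2 change of at least 1 they were 169, 346, 359, 234 and 48.

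Leaving out a library gave 204 to 360 genes for dsxRNAi in females, 856 to 1195 in males, 1325 to 1890 for sex in controls, 637 to 1145 for sex under dsxRNAi and 33 to 127 for the interaction, with fewer samples in each fit. The highest interaction count, 127, came without dsxRNAi male 2, and the cause was not tested. The dsx change ranged from -0.15 to 0.07 in females and from -0.70 to -0.49 in males. The calls shared by both sexes ranged from 162 to 249. The difference along the sex axis ranged from -0.222 to -0.0993 in females and from 0.339 to 0.453 in males.

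Camera with an estimated correlation, a stricter test where genes of a list vary together, called 0 lists for dsxRNAi in females, 1 in males, 0 for sex in controls, 1 for sex under dsxRNAi and 2 for the interaction, against 5, 15, 14, 16 and 11 with the preset correlation. fry, which asks a different question, called 1, 21, 17, 13 and 14 lists in the same order. With a replicate block camera called 8 lists for dsxRNAi in females, and the block gave 328, 1452, 1994, 1468 and 67 genes. Replicate numbers were not taken to pair the libraries, since 8 of 18 correlated best with their own number and the correlations ran from -0.299 to 0.208. All 3 numbers matched best between control and dsxRNAi females (0.106, 0.113 and 0.0244) and between dsxRNAi females and control males (0.157, 0.156 and 0.208), so a shared source of some numbers stays open. In the simulations small changes were often missed, with 30% of log2 changes of 0.5 recovered for dsxRNAi in males and 6% for the interaction. The simulated data held fewer changed genes than the 1418 called in males, so an adjusted p under 0.05 needed a smaller unadjusted p there. The 30% may therefore understate recovery in the real male contrast, where the called genes had a median absolute log2 change of 0.529.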

Other observations

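The comparison of Syt4, Cngl and CG32850 and the tests with a library left out for list counts were chosen after the result was seen.

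Single genes of metal handling and of the acid region of the gut differed between the sexes. Fer1HCH and Fer2LCH, the subunits of the iron store ferritin, whose gene models overlap on 3R, were 1.81-fold and 1.74-fold lower in control females than in control males (1644 ± 128 against 2976 ± 425 CPM, and 1710 ± 129 against 2976 ± 471 CPM, adjusted p = 0.000781 and 0.0014). Of 14 metal handling genes 3 were lower in control females, 5 adjusted over the list alone (camera adjusted p = 0.0337, adjusted p = 0.27 with an estimated correlation). lab, the homeotic gene that specifies acid-secreting copper cells (3R, 6661427 to 6678590), was 1.55-fold higher in control females (23.0 ± 1.60 against 14.9 ± 2.28 CPM, adjusted p = 0.00254). Copper cell markers had 2 of 3 higher in control females, 3 adjusted over the list alone, with 1 without control male 2 or control male 3 (camera adjusted p = 0.0104, adjusted p = 0.299 with an estimated correlation). Regional transcription factors had 3 of 14 higher, 3 adjusted over the list alone, with 1 without control female 3 or control male 1, and 1 lower, 2 adjusted over the list alone, with 0 without control female 1 or 3 or control male 1, 2 or 3 (camera adjusted p = 0.704).

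Single genes of immune and growth signalling were called under dsxRNAi in males. Of 12 antimicrobial and Imd pathway genes 3 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 5.8e-05, adjusted p = 0.288 with an estimated correlation). PGRP-SC2, an amidase that dampens immune signalling (2R, 8716950 to 8717695), rose 2.32-fold from 638 ± 28.6 to 1482 ± 440 CPM, and the receptor gene PGRP-LC (3L, 9338810 to 9348336) fell 1.33-fold from 47.3 ± 3.93 to 35.5 ± 0.766 CPM (adjusted p = 0.00689 and 0.00627). Of 11 JAK-STAT and EGF receptor genes 3 fell, 3 adjusted over the list alone (camera adjusted p = 0.121), among them sty, a feedback inhibitor of EGF receptor signalling (3L, 3401153 to 3424935), from 81.7 ± 11.1 to 57.2 ± 6.60 CPM (adjusted p = 0.0053). Of 11 insulin and TOR genes 1 rose and 4 fell, 2 and 5 adjusted over the list alone, with 0 falling without dsxRNAi male 2, dsxRNAi male 3 or control male 2 and 1 without control male 3 (camera adjusted p = 0.417).

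Sugar sensing and glycolysis had 7 of 22 genes lower and 1 higher in control females, 9 and 1 adjusted over the list alone, with 4 lower without control female 3, control male 1 or control male 3 (camera adjusted p = 0.00402, adjusted p = 0.27 with an estimated correlation). A few markers of tissues around the gut were called by sex too. Visceral muscle had 4 of 15 lower in control females, 8 adjusted over the list alone (camera adjusted p = 0.0184, adjusted p = 0.557 with an estimated correlation). Neurons had 3 of 5 lower, 3 adjusted over the list alone, with 1 without control female 1 or 3 or control male 1 or 3 (camera adjusted p = 0.0516). Fat body and hemocytes had 2 of 8 higher, 2 adjusted over the list alone, with 1 without control female 2 or 3 or control male 1 or 2 (camera adjusted p = 0.0264, adjusted p = 0.299 with an estimated correlation). Trachea had 1 of 4 lower, 1 adjusted over the list alone, with 0 without control female 1 or 3 or control male 1, 2 or 3 (camera adjusted p = 0.745). Ovary markers had 0 of 5 called by edgeR in this contrast, with 2 lower at an unadjusted p under 0.05, 0 by DESeq2 and 2 adjusted over the list alone. Cell cycle genes had 0 of 23 called by edgeR, with 1 lower at an unadjusted p under 0.05 and 1 by DESeq2.

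In dsxRNAi males edgeR called 0 of 35 proteasome genes, with 2 higher at an unadjusted p under 0.05 and 0 by DESeq2, and camera's direction was down (adjusted p = 0.0354, adjusted p = 0.737 with an estimated correlation) while the median and mean log2 changes were above 0 (0.04 and 0.04). Enterocyte markers had 0 of 7 called by edgeR, with 1 higher at an unadjusted p under 0.05 and 2 by DESeq2. The testis list had 1 of 3 lower, 1 adjusted over the list alone, the gene topi, from 8.48 ± 2.06 to 5.13 ± 0.152 CPM. Of the genes marked or driven in the genotypes 1 of 3 tested, y, was called, 2 adjusted over the list alone, with 2 without dsxRNAi male 3, and y stood at 0.00737 CPM in control males and 0.352 ± 0.110 CPM in dsxRNAi males. Of the 11 Y-linked genes and the 20 accessory gland genes in the table, 0 passed the expression filter and none was tested.

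Syt4, Cngl and CG32850 were singled out after their values were seen. Syt4, a vesicle protein gene, stood at 24.8 ± 3.34 CPM in control females and 26.6 ± 2.41 CPM in control males, and at 0.0323 and 0.0954 CPM in the dsxRNAi groups, with 4 and 10 counts in all. CG32850 stood at 31.6 ± 1.29 and 36.1 ± 0.555 CPM in the control groups and at 119 ± 10.4 and 134 ± 2.18 CPM in the dsxRNAi groups. Cngl, an ion channel gene, stood at 28.6 ± 7.96 and 24.6 ± 1.64 CPM in the female groups and at 0.0384 and 0.0368 CPM in the male groups.

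For the contrasts of 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. The real split called 335 genes for dsxRNAi in females, with 2 as the highest of the others, and 1418 in males, 1937 for sex in controls and 1436 for sex under dsxRNAi, with 0 as the highest of the others in each. In each of these 4 contrasts 1 split of the 10 gave as many genes. For lists the real split called 5, 15, 14 and 16, with 12, 14, 16 and 18 as the highest of the others, and 9, 1, 3 and 3 of the 10 splits gave as many. For the difference along the sex axis in females 46 of 100 splits gave a value as low as -0.111, with -0.305 as the lowest of the others, so chance cannot be excluded.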
